A study of Arabidopsis thaliana with 24 samples.

How the data were processed

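The deposited values are log2 signals of Affymetrix ATH1 arrays, and the submitters' notes name GCOS 1.4 as processing software. On the total-RNA arrays the lowest value was a floor at a signal of 1. Trimmed means of the signal left out 2% at each end. On the polysomal arrays the tied lowest value showed that each array had been divided by 1 factor. Within groups, arrays correlated at r = 0.94 to 0.97 across probe sets, and 0 columns were identical.

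Of 22810 probe sets, 64 controls and the 25% of the rest with the lowest mean were left out, and 17059 were tested. The probe table used here names 14016 probe sets, 13513 with 1 gene and 503 with several, and 8794 carry no name. Gene values come from probe sets with 1 gene, of which 9513 were tested. Group means of all 24 arrays were fitted with limma 3.58.1 in R 4.3.3, with an intensity trend in the variance prior and Benjamini-Hochberg adjustment at 0.05 in each of 16 comparisons. Polysome loading is the polysomal minus the total mean, and the light-by-genotype comparisons are the light change in dcp5-1 minus that in control. Replicate numbers paired the samples: residual correlations of the same number in the 12 pairs of groups compared directly were 0.22 to 0.61 pooled over numbers, and 0.15 at the lowest. Replicate number as an additive replicate block gave 428 calls for dcp5-1 against control in dark total RNA, against 98. Array medians were compared by exact two-sided permutation tests, and later by sign flips within replicate numbers.

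Gene lists were tested with camera of limma at a preset correlation of 0.01 and with an estimated correlation, adjusted over the 24 lists with at least 2 tested members in each comparison. Of these tests 87 of 384 passed, and 2 passed with an estimated correlation. The comparisons, tests, named-gene rule and 18 of the lists were set before the data were examined. A further 10 lists were drawn from the gene table before gene values were compared, and 1 list was written after the named genes were seen. List values are medians relative to the median of all probe sets, with 1 probe set per gene. Tested were 2 of 17 listed flavonoid, 2 of 28 dark growth, 2 of 16 heat shock and 9 of 28 chlorophyll genes. Their list results cover these alone. The named-gene rule took, per comparison, the 8 highest and 8 lowest changes that passed the test with no overlap of replicates, and up to 4 members of each list with the smallest adjusted p. Not every such gene is printed. Lack of overlap also fixes the direction of all replicate pairs. Giving polysomal and loading values of genes and lists from arrays centred on their median was decided after the array-wide offsets were seen. Counts come from the deposited values first, and total-RNA values are as deposited.

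On simulated data with known changes and no array offsets, the fit called 43.3% of 67 changes of log2 1 and 87.9% of 66 changes of log2 2 for light in control total RNA. With the array offsets kept these were 2.99% and 84.8%, because the fit shares its spread across arrays. For the light-by-genotype comparison in total RNA the shares at log2 2 were 69.7% and 47.0%. For polysome loading in control light, with the offsets kept, the fit made 10538 calls in unchanged probe sets. With the offsets removed it called 14.9% of 67 changes of log2 1 and 75.8% of 66 changes of log2 2. The alternatives were quantile normalisation, median centring, the replicate block, other filters on dim probe sets, fits on the compared groups alone, no variance trend, array weights, fraction pairs, and leaving out each array or replicate number.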

Results

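Total RNA and polysome-bound RNA were profiled on 24 Affymetrix ATH1 arrays from the aerial parts of 4-d-old etiolated Arabidopsis seedlings, kept in the dark or given 4 h of white light. The control was the accession Col-0, and dcp5-1 is a mutant of DCP5, a component of processing bodies, the cytoplasmic granules that hold mRNAs out of translation. The 2 genotypes, 2 light conditions and 2 RNA fractions made 8 groups of 3 biological replicates. Trimmed means of the signal were 495.5 to 496.3 on total-RNA arrays, but 67.3 to 345.5 on polysomal arrays. Each polysomal array had been divided by a factor of its own, from 1.42 to 7.32. With that factor undone the trimmed means were 490.2 to 492.6. The median polysomal signal relative to total RNA was -2.22 ± 0.63 (log2, SD, n = 3) in dark control, -0.97 ± 0.21 in light control, -1.33 ± 0.25 in dark dcp5-1 and -0.96 ± 0.28 in light dcp5-1. Light control lay above dark control by 1.25, with no overlap of the 3 pairs, and dark dcp5-1 lay above dark control by 0.89. Exact two-sided permutation tests gave p = 0.10 for each of these, the smallest that 3 against 3 allows. They ignore the pairing by replicate number, within which the differences were 0.93 to 1.73 and 0.52 to 1.32, all above 0 (exact sign-flip p = 0.25, the smallest that 3 pairs allow). The light difference in dcp5-1 was 0.37 (exact permutation p = 0.30), and the genotypes in light differed by 0.0065 (exact permutation p = 1). Because this array-wide shift moves every gene alike, polysomal and loading values of genes and lists are given below relative to the array median. The comparisons address which transcripts light changes, and how loss of DCP5 alters their levels, light response and polysome loading. The array-wide plot shows the 12 pairs. Where leaving out single arrays ended calls, the arrays are given below by the part of their group that sets them apart and their replicate number, with the highest adjusted p.

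**Figure D1:**
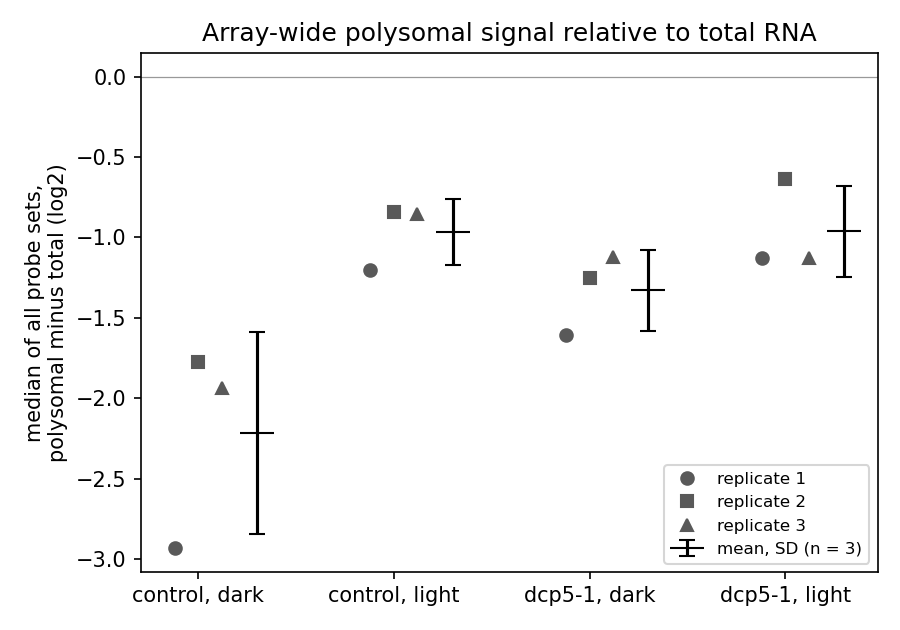
Median over all probe sets of the polysomal minus the total signal (log2) for each replicate pair (points, shaped by replicate number), with mean and SD (n = 3) beside them, for control and dcp5-1 in dark and light. The 3 dark control pairs, from -2.93 to -1.78, lie below the other 9 pairs.

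No probe set names DCP5 in the gene table used here, so its level was not analysed and the genotype labels were not checked by it.

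Light changed photosynthesis, pigment and growth genes in total RNA of control seedlings. The largest rises were in THI2.2 (6.66 ± 0.49), MSRB6 (6.42 ± 0.36), AT3G57020 (6.15 ± 0.28) and AT3G52740 (5.62 ± 0.61), as log2 change with SE and 3 arrays in each group. THI2.2 is a thionin, MSRB6 a methionine sulfoxide reductase and AT3G52740 the cryptochrome inhibitor BIC1. The largest falls were in AT2G34020 (-5.82 ± 0.33), XTH19 (-5.22 ± 0.49) and GH9B13 (-5.01 ± 0.37), the second being a xyloglucan endotransglucosylase of the cell wall and the third a glycosyl hydrolase. All 3 tested light-harvesting genes, of 20 listed, rose, LHCB4.3 by 2.45 ± 0.34 or 5.45-fold. All 5 tested photosystem and electron transport subunits, of 30 listed, rose, among them PSBY (2.40 ± 0.28) and PSAN (2.298 ± 0.29). All 3 tested Calvin cycle genes, of 19 listed, rose. They were RCA (1.88 ± 0.29), SBPASE (1.84 ± 0.29) and PRK (1.15 ± 0.33), which encode Rubisco activase, sedoheptulose bisphosphatase and phosphoribulokinase. Adjusted over the list alone, these counts were 3, 5 and 3. Of 9 chlorophyll and tetrapyrrole genes 4 rose, including HEME1 (1.79 ± 0.28) and CHLI2 (1.80 ± 0.29), and 1 fell, PORB by 1.49 ± 0.29, with 5 and 1 adjusted over the list alone. Of 27 thylakoid assembly and redox genes 21 rose, CaS by 2.95 ± 0.36, and 1 fell. The call of PRK (dark 2 or 3, light 1, p 0.15) ended without single arrays.

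Flavonoid genes rose in light in control total RNA, with UF3GT at 4.88 ± 0.62 and DFR, dihydroflavonol reductase, at 4.45 ± 0.66, while UGT78D2, a flavonoid glucosyltransferase, rose by 3.72 ± 0.33. Among light signalling and clock genes, HYH, a bZIP factor related to HY5, rose by 3.43 ± 0.35, FHL, a partner of phytochrome A, fell by 2.92 ± 0.31, and the clock gene GI rose by 1.46 ± 0.30. Of 22 expansins and xyloglucan endotransglucosylases, below called the expansin list, 11 fell, such as EXPA9 (-3.62 ± 0.30), and 3 rose, such as EXPB3 (3.50 ± 0.45). Both dark growth genes, EXPA8 (-1.59 ± 0.26) and IAA29 (-2.14 ± 0.43), fell, and both were called adjusted over the list alone. Of 13 auxin genes 5 fell, including the conjugating enzymes GH3.3 (-3.34 ± 0.34) and WES1 (-1.77 ± 0.30), and 1 rose. Of 7 tubulins 4 fell, TUB1 by 2.56 ± 0.37. Other called genes were LTI30 (2.05 ± 0.37), COR27 (-2.54 ± 0.49) and AT1G53540 (1.45 ± 0.34), of which LTI30 is a dehydrin and AT1G53540 a small heat shock protein, and ICL (-1.64 ± 0.36), isocitrate lyase of storage lipid use. Every gene named for this comparison had no overlap of replicates, with adjusted p from 4.8e-15 to 0.015.

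In the list tests for light in control total RNA, the adjusted p was 0.0014 for light-harvesting genes (median 1.43 relative to all probe sets), 1.6e-06 for photosystem subunits (1.59), 0.0014 for the Calvin cycle (1.88), 0.0014 for flavonoid synthesis (4.71) and 0.0060 for dark growth (-1.83). With an estimated correlation each of these 5 had adjusted p = 0.12. Thylakoid genes had a relative median of 1.19 (adjusted p = 2.2e-13), and chlorophyll genes 0.74 (adjusted p = 0.034, lost at adjusted p = 0.057 on centred values, 0.061 with quantile normalisation and 0.056 with the compared groups alone). With an estimated correlation these lists had adjusted p = 0.12 and 0.67. The expansin list had relative median -1.28, adjusted p = 0.0024, 0.67 with an estimated correlation. Auxin genes had relative median -0.32, adjusted p = 0.037, adjusted p = 0.67 with an estimated correlation, lost at adjusted p = 0.057 on centred values, 0.061 with quantile normalisation, 0.094 with the compared groups alone, 0.067 with no variance trend and 0.12 with array weights (median 0.017), the median being -1.70 with the lower 50% left out. Tubulins had relative median -0.77, adjusted p = 0.0036, 0.48 with an estimated correlation. The 123 cytosolic ribosomal protein genes had relative median 0.28, adjusted p = 0.030, 0.88 with an estimated correlation, 4 called and 103 above 0. Of 27 listed processing body and mRNA decay genes 10 were tested (list adjusted p = 0.46). Of these, limma called 0 and 0 had unadjusted p under 0.05, but most changes of log2 1 escape a call (2.99% called when simulated). In all, limma called 1656 probe sets higher and 1333 lower of 17059 tested, 55.4% higher. Centred arrays gave 2356 and 2768, 46.0% higher. The count was 1730 and 1362 without replicates 2 and 3. Calls of chlorophyll genes (dark 2, light 1, p 0.11), ribosomal protein genes (dark 1, light 1, p 0.30) and auxin genes (dark 2, light 1, p 0.080) ended without single arrays.

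In polysomal RNA of control seedlings, light raised photosynthesis and pigment genes and lowered cell wall genes relative to the array median. The largest relative rises were in THI2.2 (8.72 ± 0.60), MSRB6 (6.21 ± 0.23) and ECS1 (5.96 ± 0.32), and the largest falls in AT2G34020 (-5.50 ± 0.28), XTH19 (-5.14 ± 0.42) and EXPA9 (-3.77 ± 0.21) (log2, SE, n = 3 and 3). All 3 light-harvesting genes rose, LHCB4.3 by 2.55 ± 0.18 (relative median 1.94, adjusted p = 2.7e-04, adjusted p = 0.019 with an estimated correlation, and 0.055 with it and the block, 3 higher adjusted over the list alone). All 5 photosystem subunits rose, PSBY by 2.44 ± 0.26 (relative median 1.39, adjusted p = 2.7e-05, adjusted p = 0.16 with an estimated correlation, 5 higher adjusted over the list alone). Of 3 Calvin cycle genes 2 rose, RCA by 1.80 ± 0.23, while PRK was at 0.75 ± 0.38 (adjusted p = 0.15, and 0.016 with replicate number as a block). The Calvin cycle list had relative median 1.63, adjusted p = 0.014, 0.25 with an estimated correlation, 2 higher adjusted over the list alone. Of 27 thylakoid genes 19 rose and 1 fell (relative median 1.12, adjusted p = 4.5e-10, 0.19 with an estimated correlation). Both flavonoid genes rose, UF3GT (4.82 ± 0.52) and DFR (3.75 ± 0.59) (relative median 4.34, adjusted p = 0.0052, adjusted p = 0.16 with an estimated correlation, 2 higher adjusted over the list alone), as did UGT78D2 (3.45 ± 0.23), CHLM (1.79 ± 0.27) and HYH (3.79 ± 0.28), CHLM being a chlorophyll methyltransferase. FHL fell by 2.15 ± 0.25.

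Of 123 cytosolic ribosomal protein genes 28 rose in polysomal RNA of control seedlings, AT3G06680 by 1.26 ± 0.22, and 0 fell (relative median 0.42, adjusted p = 1.0e-05, adjusted p = 0.56 with an estimated correlation). Of the 22 in the expansin list 12 fell and 3 rose, the latter including EXPB3 (3.27 ± 0.35) and XTH32 (3.11 ± 0.32) (relative median -1.38, adjusted p = 0.0020, adjusted p = 0.24 with an estimated correlation, the median being -0.54 with no dim filter). Among auxin genes GH3.3 fell by 3.19 ± 0.21 and GH3.9 rose by 2.45 ± 0.41. Of 7 tubulins 5 fell, TUB1 by 2.76 ± 0.28 (relative median -0.85, adjusted p = 0.0011, 0.16 with an estimated correlation). Both dark growth genes fell (relative median -1.76, adjusted p = 0.0076, adjusted p = 0.094 with an estimated correlation, 2 lower adjusted over the list alone). Of 66 plastid-encoded genes 6 rose, psbC by 1.43 ± 0.44. With replicate number as a block the plastid-encoded, chlorophyll and plastid ribosomal protein lists passed, at adjusted p = 0.034, 0.045 and 0.038, from 0.11, 0.13 and 0.062 without it. These 3 had adjusted p = 0.36 to 0.62 with the block and an estimated correlation. ICL fell by 1.74 ± 0.34 and the lipase gene SDP1 by 0.84 ± 0.20 relative to the array median, but as deposited ICL was at -0.47 (adjusted p = 0.23) and SDP1 at 0.44 (adjusted p = 0.19). Each gene named except PRK passed limma with adjusted p of 0.017 or less. Deposited values gave 13043 probe sets higher and 267 lower, 98.0% higher, around a median shift of 1.23. Centred arrays gave 2308 and 2652, 46.5% higher. The call of psbC (dark 3, light 1, p 0.095) ended without single arrays.

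For polysome loading, the polysomal minus total difference, no gene of control seedlings passed the test for light relative to the array median. SAG29 was at 2.64 ± 1.14, AT5G34790 at 2.72 ± 0.93, LHCB4.3 at 0.14 ± 0.26 and UF3GT at -0.028 ± 0.74, each with adjusted p = 1, and UF3GT moved the stated way in 1 of 3 pairs. As deposited the same 4 were at 3.89, 3.97, 1.38 and 1.22, with adjusted p = 0.016, 0.010, 0.020 and 0.19. The 123 ribosomal protein genes had relative median 0.14, adjusted p = 0.0033, adjusted p = 0.91 with an estimated correlation, lost at adjusted p = 0.052 as deposited and 0.24 with quantile normalisation (median 0.070), with 89 above 0. Plastid-encoded genes had a relative median of 0.24 (adjusted p = 0.23, 0.0021 with the block, adjusted p = 0.82 with the block and an estimated correlation). limma called 11354 probe sets higher and 0 lower as deposited, around a median shift of 1.25, and 0 on centred values, where 365 had an unadjusted p under 0.05. Pairing the fractions gave 13860 and 2 as deposited and 0 on centred values. The count was 5151 without control polysomal dark 1. It was 7233 and 0 without replicates 2 and 3. The call of ribosomal protein genes (polysomal dark 1, polysomal light 1 or 3, total dark 2, total light 2 or 3, p 0.86) ended without single arrays.

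In dcp5-1 seedlings light also raised photosynthesis and pigment genes of total RNA. The largest rises were in THI2.2 (7.57 ± 0.49), MSRB6 (5.69 ± 0.36), AT3G56290 (5.18 ± 0.45) and AT3G57020 (5.14 ± 0.28), and the largest falls in AT2G34020 (-4.45 ± 0.33), GH9B13 (-3.94 ± 0.37) and XTH19 (-3.82 ± 0.49) (log2, SE, n = 3 and 3). Of 3 light-harvesting genes 2 rose, LHCB4.3 by 1.57 ± 0.34 (relative median 1.07, adjusted p = 0.0080, 3 higher adjusted over the list alone), of 5 photosystem subunits 4 rose, PSBY by 1.79 ± 0.28 (relative median 1.105, adjusted p = 3.0e-05, 5 higher adjusted over the list alone), and of 3 Calvin cycle genes 2 rose, RCA by 1.51 ± 0.29 (relative median 1.56, adjusted p = 0.0014, 3 higher adjusted over the list alone). These lists had adjusted p = 0.19 with an estimated correlation. Of 27 thylakoid genes 11 rose, CaS by 2.19 ± 0.36, and 1 fell (relative median 0.86, adjusted p = 1.3e-09, adjusted p = 0.30 with an estimated correlation). The flavonoid genes UF3GT (4.49 ± 0.62) and DFR (3.04 ± 0.66) rose (relative median 3.81, adjusted p = 0.0014, adjusted p = 0.19 with an estimated correlation, 2 higher adjusted over the list alone). Also higher were HYH (3.22 ± 0.35), GI (1.77 ± 0.30) and ECS1 (1.93 ± 0.37), and lower were FHL (-2.79 ± 0.31), GH3.3 (-3.50 ± 0.34), IAA29 (-2.00 ± 0.43) and TUB1 (-1.59 ± 0.37). These genes and the others named had adjusted p from 2.9e-13 to 0.0038. EXPA8 was at -0.38 ± 0.26 (adjusted p = 0.46).

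Of the 22 in the expansin list 7 fell and 2 rose in dcp5-1 total RNA (relative median -0.64, adjusted p = 0.030, adjusted p = 0.78 with an estimated correlation). Of 13 auxin genes 5 fell and 1 rose (relative median -0.13, adjusted p = 0.020, adjusted p = 0.63 with an estimated correlation, lost at adjusted p = 0.078 with no dim filter (median 0.19), the median being -0.079 with array weights and -1.88 with the lower 50% left out). Of 7 tubulins 1 fell (relative median -0.60, adjusted p = 0.030), and of 34 UDP-glycosyltransferases 5 rose and 1 fell (relative median 0.26, adjusted p = 0.044, lost at adjusted p = 0.061 on centred values, 0.062 with quantile normalisation, 0.066 with the compared groups alone and 0.069 with array weights). They had adjusted p = 0.63 and 0.78 with an estimated correlation. Over all probe sets 1177 rose and 822 fell in limma, 58.9% higher, and centred arrays gave 1835 and 1896, 49.2% higher. Across genes, which are not independent replicates, the changes correlated with those of control at r = 0.89, and 1085 probe sets rose in both genotypes and 703 fell in both, against 114.3 and 64.2 for independent lists. The count was 1006 and 764 without replicates 2 and 3. The median of auxin genes turned to 0.042 without light replicate 2, with the call kept. Calls of the expansin list (dark 2 or 3, p 0.054), UDP-glycosyltransferases (dark 2, light 3, p 0.11) and tubulins (dark 1 or 3, light 3, p 0.071) ended without single arrays.

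In polysomal RNA of dcp5-1, light raised MSRB6 (5.99 ± 0.23), THI2.2 (5.91 ± 0.60), AT3G44450 (4.75 ± 0.30) and AT3G52740 (4.52 ± 0.53) and lowered AT5G12940 (-4.34 ± 0.51), AT2G34020 (-4.26 ± 0.28) and XTH19 (-3.51 ± 0.42) relative to the array median. AT3G44450 is the cryptochrome inhibitor BIC2. All 3 light-harvesting genes rose, LHCB4.3 by 1.65 ± 0.18 (relative median 1.56, adjusted p = 8.6e-04, adjusted p = 0.030 with an estimated correlation, and 0.095 with it and the block, 3 higher adjusted over the list alone). All 5 photosystem subunits rose, PSBY by 1.96 ± 0.26 (relative median 1.18, adjusted p = 5.9e-05, 5 higher adjusted over the list alone), as did all 3 Calvin cycle genes (relative median 1.54, adjusted p = 0.0068, 3 higher adjusted over the list alone). With an estimated correlation these lists had adjusted p = 0.24. Of 27 thylakoid genes 18 rose (relative median 0.86, adjusted p = 8.2e-09, 0.24 with an estimated correlation). Of 66 plastid-encoded genes 8 rose, 63 being above 0 (relative median 0.52, adjusted p = 0.0012, 0.71 with an estimated correlation). Of 123 ribosomal protein genes 6 rose and 1 fell (relative median 0.22, adjusted p = 0.011, adjusted p = 0.71 with an estimated correlation, lost at adjusted p = 0.15 with quantile normalisation (median 0.14)). Of 7 tubulins 5 fell, TUB1 by 1.60 ± 0.28 (relative median -0.65, adjusted p = 0.0029), and of 13 auxin genes 5 fell, GH3.3 by 3.45 ± 0.21 (relative median -0.61, adjusted p = 0.016, the median being -1.34 with the lower 50% left out). These lists had adjusted p = 0.24 with an estimated correlation. Both dark growth genes fell (relative median -1.46, adjusted p = 0.016, adjusted p = 0.16 with an estimated correlation, 2 lower adjusted over the list alone). UF3GT rose by 2.13 ± 0.52, DFR by 1.86 ± 0.59, HYH by 3.29 ± 0.28 and ECS1 by 2.05 ± 0.32. All genes named passed with adjusted p of 0.027 or less. With the replicate block the flavonoid, chlorophyll, plastid ribosomal protein, expansin and UDP-glycosyltransferase lists passed, at adjusted p = 0.044, 0.040, 0.040, 0.040 and 0.040, from 0.063, 0.16, 0.062, 0.056 and 0.056 without it. These 5 had adjusted p = 0.14 to 0.48 with the block and an estimated correlation. Calls of DFR (dark 1 or 3, light 2 or 3, p 0.13), ribosomal protein genes (dark 1, light 2, p 0.31) and plastid-encoded genes (dark 3, light 2, p 0.095) ended without single arrays.

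Deposited values of dcp5-1 polysomal RNA gave 2287 probe sets higher and 390 lower in light, 85.4% higher, around a shift of 0.34, and centred arrays gave 1775 and 1803, 49.6% higher. The count was 4069 without control polysomal dark 1 and 1767 without dcp5-1 polysomal light 2. It was 1214 and 1379 without replicates 2 and 3.

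Polysome loading of single genes in dcp5-1 did not pass the test in light. The flavonoid genes UF3GT and DFR were at -2.34 ± 0.74 and -1.17 ± 0.84, lower in 3 of 3 pairs, and as a list had relative median -1.76, adjusted p = 0.0016, adjusted p = 0.29 with an estimated correlation, 1 lower adjusted over the list alone. Plastid-encoded genes had relative median 0.63, adjusted p = 2.2e-10, 0.92 with an estimated correlation, 62 of 66 being above 0. Examples were ndhG (2.14 ± 1.52), psaC (1.54 ± 1.304) and petD (1.51 ± 1.098), with ndhG higher in 2 of 3 pairs. Ribosomal protein genes had relative median 0.14, adjusted p = 2.6e-04, 0.98 with an estimated correlation, lost at 0.088 with quantile normalisation (median 0.091). limma called 0 probe sets as deposited, with 503 at an unadjusted p under 0.05, and 0 on centred values, with 341. Pairing the fractions on centred values gave 0 calls, with 1018. The call of ribosomal protein genes (polysomal dark 1, polysomal light 2, total dark 2, p 0.64) ended without single arrays.

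**Figure D2:**
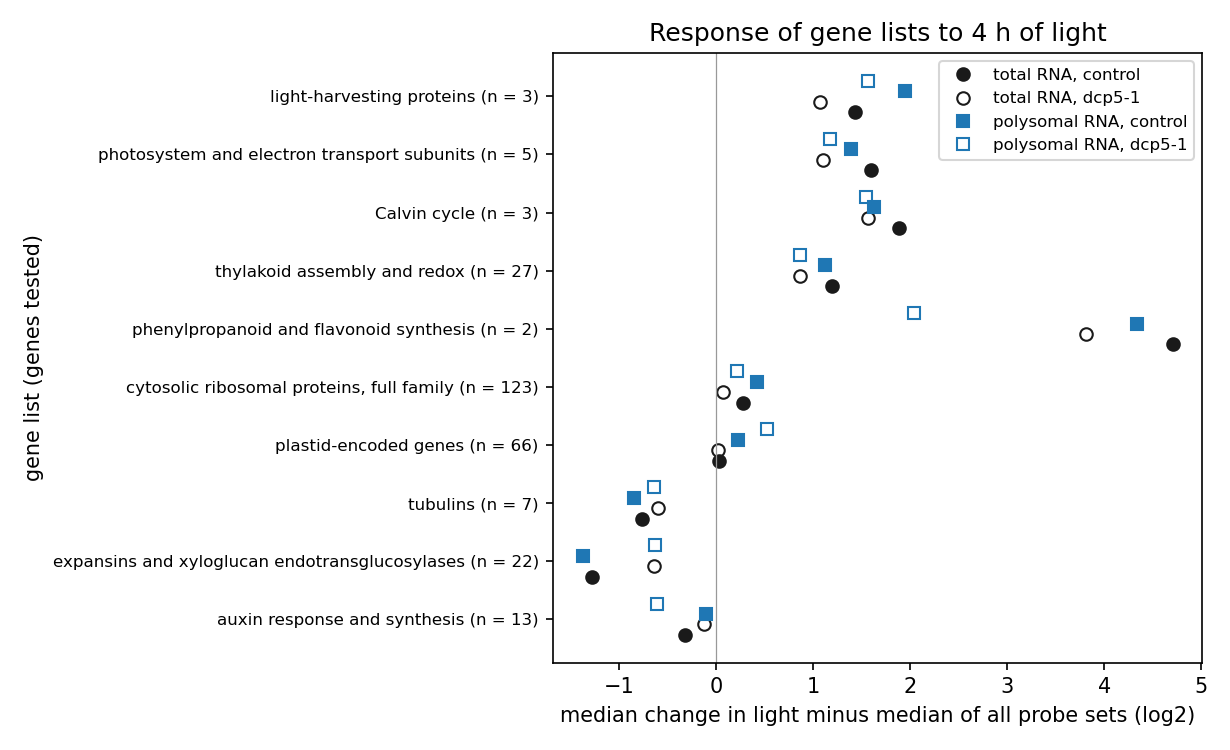
Median light response of 10 gene lists relative to the median of all probe sets (log2, horizontal axis), in total RNA (circles) and polysomal RNA (squares) of control (filled) and dcp5-1 (open), with the number of genes tested beside each list. Light-harvesting, photosystem, Calvin cycle, thylakoid and flavonoid lists lie above 0 in all 4 comparisons, and tubulins lie below 0.

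In dark total RNA, dcp5-1 against control gave 98 calls, and 1137 if centred with the block. AT3G50400, AT4G38080 and AT4G36430, the last a class III peroxidase, were higher by 4.63 ± 0.94, 4.14 ± 0.77 and 3.69 ± 0.58 (log2, SE, n = 3 and 3). AT2G16005, AT1G66800 and AT5G38030, the last a MATE transporter, were lower, at -4.51 ± 0.34, -3.18 ± 0.55 and -3.11 ± 0.38. These 6 had adjusted p from 2.2e-09 to 0.013. AT1G53540, a small heat shock protein, was higher by 2.49 ± 0.34 (adjusted p = 9.7e-05), UGT71C1 was lower at -1.63 ± 0.37 (adjusted p = 0.031), and AT1G30870, a peroxidase, was higher by 2.45 ± 0.49 (adjusted p = 0.011). These 9 moved the stated way in 3 of 3 pairs. Of 10 cold and dehydration genes 0 passed limma over all probe sets, 3 had an unadjusted p under 0.05 and 3 passed adjusted over the list alone: LEA4-5 (1.46 ± 0.44), LEA18 (1.49 ± 0.51) and AtLEA4-1 (1.16 ± 0.39) (adjusted p = 0.19, 0.31 and 0.31, and 0.015, 0.019 and 0.033 with the block). This list had relative median 0.44, adjusted p = 3.0e-04, 0.20 with an estimated correlation. The 2 heat shock genes had relative median 1.49, adjusted p = 9.8e-05, 0.054 with an estimated correlation, and 0.045 with it and the block. Adjusted over the list alone 1 was higher, 1 being called. With no dim filter the call of UGT71C1 ended (adjusted p = 0.069). Calls of AT3G50400 (control 2, dcp5-1 2 or 3, p 0.11), AT4G38080 (dcp5-1 2 or 3, p 0.069), UGT71C1 (control 2 or 3, dcp5-1 2 or 3, p 0.24), AT1G30870 (control 1 or 2, dcp5-1 2 or 3, p 0.10) and cold and dehydration genes (control 2, p 0.053) ended without single arrays.

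Of 123 ribosomal protein genes 119 were above 0 in dark dcp5-1 total RNA (relative median 0.33, adjusted p = 1.1e-10), and the 14 of the shorter list had relative median 0.34, adjusted p = 3.0e-04. They had adjusted p = 0.76 with an estimated correlation. Examples were AT3G53890 at 0.69 ± 0.32 and AT3G28500 at 2.49 ± 0.69, with adjusted p = 0.76 and 0.13 as deposited and 0.032 and 0.019 on centred values. AT3G28500 had adjusted p = 0.0061 with the block. Plastid-encoded genes had relative median -0.37, adjusted p = 3.0e-04, 0.76 with an estimated correlation, rpl36 being at -0.66 ± 0.35 (adjusted p = 0.91). Photosystem subunits had relative median 0.46, adjusted p = 0.0074, 0.66 with an estimated correlation, PSAN being at 0.57 ± 0.29 (adjusted p = 0.83). ATG8 and ATG3 genes had relative median 0.25, adjusted p = 0.035, 0.76 with an estimated correlation, lost at 0.056 with the block. Processing body and mRNA decay genes had a relative median of -0.033 (adjusted p = 0.96), with 0 called by limma and 0 at an unadjusted p under 0.05. The 2 measured root markers had a relative median of 0.78 (adjusted p = 0.14). Among genes of root tissue, EXPA18 was at 1.59 ± 0.49 (adjusted p = 0.21, 0.038 with the block), the beta-glucosidase PYK10 at -0.061 ± 0.28 in 2 of 3 pairs, and the peroxidase AT4G11290 at -1.41 ± 0.36 (adjusted p = 0.077, 0.0036 with the block and 0.0067 on centred values). limma called 74 probe sets higher and 24 lower, 75.5% higher. It called 308 and 120 with the block, and 270 and 163 on centred values, 62.4% higher. The count was 249 without control polysomal dark 1, 53 without control total dark 1, 44 without control total dark 2, 38 without dcp5-1 total dark 2 and 37 without dcp5-1 total dark 3. It was 364, 9 and 26 without replicates 1, 2 and 3. With array weights PYK10 was at 0.019. Calls of photosystem subunits (control 2, dcp5-1 1, p 0.29), ATG8 and ATG3 genes (control 2 or 3, dcp5-1 1 or 2, p 0.097) and plastid-encoded genes (control 2, dcp5-1 3, p 0.99) ended without single arrays.

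In dark polysomal RNA relative to the array median, dcp5-1 had higher AT3G50400 (5.47 ± 0.85), PRX52 (5.36 ± 1.08), AT5G24240 (3.902 ± 0.57) and AT1G53540 (2.52 ± 0.21) and lower AT2G16005 (-3.899 ± 0.43), AT1G66800 (-3.34 ± 0.47) and AT5G38030 (-2.57 ± 0.28) (log2, SE, n = 3 and 3, in 3 of 3 pairs). PRX52 is a peroxidase. XTH16 was higher by 1.23 ± 0.23 and AT1G30870 by 1.48 ± 0.36, and AT4G11290 was lower, at -1.48 ± 0.29. The plastid gene rps16 was at -2.19 ± 0.39 and the mitochondrial gene cox2 at -1.85 ± 0.45. These 12 had adjusted p from 1.8e-07 to 0.023. As deposited AT4G11290 and cox2 did not pass, at -0.58 and -0.96 (adjusted p = 0.15 and 0.14). Plastid-encoded genes had relative median -0.65, adjusted p = 7.4e-08, adjusted p = 0.54 with an estimated correlation, 2 of 66 being called lower, and 23 with the block. Of 123 ribosomal protein genes 110 were above 0 (relative median 0.26, adjusted p = 7.4e-08, adjusted p = 0.54 with an estimated correlation), with 0 called by limma, 21 at an unadjusted p under 0.05 and 8 with the block. The shorter ribosomal list had relative median 0.35, adjusted p = 0.0030, 0.54 with an estimated correlation. Cold and dehydration genes had relative median 0.49, adjusted p = 0.038, lost at adjusted p = 0.064 with the compared groups alone, 0.058 with no variance trend and 0.13 with no dim filter, and heat shock genes had relative median 1.21, adjusted p = 0.013, lost at adjusted p = 0.064 with the compared groups alone, 1 higher adjusted over the list alone. With an estimated correlation these lists had adjusted p = 0.54 and 0.17. As deposited limma called 10124 probe sets higher and 19 lower around a shift of 0.88, 99.8% higher. Centred arrays gave 322 and 257, 55.6% higher, and with the block also 802 and 821. The count was 2824 without control polysomal dark 1, 6050 without dcp5-1 polysomal dark 2 and 4760 without dcp5-1 polysomal dark 3. It was 6231 and 1123 without replicates 1 and 3. With the compared groups alone calls of PRX52, cox2, XTH16 and AT1G30870 ended (adjusted p = 0.051, 0.34, 0.069 and 0.090). Calls of cox2 (control 1, 2 or 3, dcp5-1 2, p 0.15), AT1G30870 (control 1, dcp5-1 2 or 3, p 0.12) and cold and dehydration genes (control 2 or 3, dcp5-1 1, p 0.31) ended without single arrays.

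For polysome loading in the dark, THI2.2 and AT1G22690 were the 2 genes called in dcp5-1 as deposited, at 4.62 ± 0.69 and 2.75 ± 0.46 (adjusted p = 0.0052 and 0.017). They were named after their values were seen. Relative to the array median they were at 3.73 ± 0.85 and 1.87 ± 0.38 (adjusted p = 0.9999 and 0.89). UF3GT was at 2.41 ± 0.74 (adjusted p = 0.9999), and the 2 flavonoid genes had relative median 1.498, adjusted p = 0.0081, adjusted p = 0.47 with an estimated correlation, lost at adjusted p = 0.52 as deposited and 0.076 with array weights, 1 higher adjusted over the list alone. Chlorophyll genes had relative median -0.26, adjusted p = 0.013, lost at adjusted p = 0.61 as deposited and 0.076 with array weights (median -0.17), and plastid-encoded genes relative median -0.32, adjusted p = 5.2e-04. These lists had adjusted p = 0.86 and 0.88 with an estimated correlation. Centred arrays gave 0 calls, with 224 probe sets at an unadjusted p under 0.05, and 0 with 661 when the fractions were paired. As deposited, with a median shift of 0.88, the block gave 4397 higher and 2 lower and pairing the fractions gave 31 and 0. The count was 4 without control polysomal dark 1 or 3, 1 without control total dark 1, dcp5-1 polysomal dark 2 or 3 or dcp5-1 total dark 3 and 6805 without control polysomal dark 2. It was 0, 0 and 1 without replicates 1, 2 and 3. Calls of chlorophyll genes (control polysomal 1, control total 2 or 3, dcp5-1 polysomal 2 or 3, dcp5-1 total 1, p 0.34), flavonoid genes (control polysomal 1, control total 2, dcp5-1 polysomal 2, p 0.18) and plastid-encoded genes (control polysomal 2, control total 3, dcp5-1 polysomal 3, dcp5-1 total 1 or 2, p 0.58, at 0.049) ended without single arrays.

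In light total RNA, AT2G23540, AT4G38080, AT5G24240 and AT4G36430 were higher in dcp5-1, by 5.35 ± 1.02, 4.47 ± 0.77, 3.898 ± 0.57 and 3.57 ± 0.58 (log2, SE, n = 3 and 3). AT2G16005, AT1G66800 and AT5G38030 were lower, at -4.23 ± 0.34, -4.09 ± 0.55 and -3.01 ± 0.38. These 7 had adjusted p from 1.0e-08 to 0.0048. AT1G30870 was higher by 2.02 ± 0.49 (adjusted p = 0.040). These 8 moved the stated way in 3 of 3 pairs. AT1G53540 was at 1.195 ± 0.34 (adjusted p = 0.11, 0.0028 with the block and 0.0010 on centred values). The expansin list had relative median 0.55, adjusted p = 8.5e-04, adjusted p = 0.89 with an estimated correlation, 18 of 22 being above 0, 0 called by limma and 5 at an unadjusted p under 0.05. XTH33, EXPA8 and EXPA18 were at 1.05 ± 0.34, 0.77 ± 0.26 and 1.003 ± 0.49 (adjusted p = 0.22, 0.26 and 0.67). XTH33 had 0.028 with the block and 0.0039 on centred values, where EXPA8 had 0.012. The 2 root markers, EXPA18 being 1, did not pass (relative median 0.51, adjusted p = 0.47). Of 10 root cell wall genes, listed after the named genes were seen (relative median 0.88), 3 were higher and 0 lower on centred values. Cold and dehydration genes had relative median 0.51, adjusted p = 1.8e-04, 0.25 with an estimated correlation, with 3 called adjusted over the list alone. LEA18 and AtLEA4-1 were at 1.98 ± 0.51 and 1.51 ± 0.39 (adjusted p = 0.056 and 0.063, 6.5e-04 and 0.0019 with the block). With no dim filter the call of AT1G30870 ended (adjusted p = 0.076). Calls of AT2G23540 (dcp5-1 2, p 0.062), AT1G30870 (control 1 or 3, dcp5-1 1, 2 or 3, dcp5-1 dark 2 or 3, dcp5-1 polysomal 3, dcp5-1 polysomal dark 3, p 0.22) and the expansin list (control 1, p 0.071) ended without single arrays.

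Plastid-encoded genes were lower as a list in light dcp5-1 total RNA (relative median -0.43, adjusted p = 1.4e-05, adjusted p = 0.89 with an estimated correlation, the median being -0.26 with array weights), with 61 of 66 not above 0. Thylakoid genes had relative median -0.25, adjusted p = 0.0073, 0.89 with an estimated correlation, NTRC being at -0.48 ± 0.28 (adjusted p = 0.81). Flavonoid genes had relative median -1.298, adjusted p = 0.045, adjusted p = 0.89 with an estimated correlation, lost at adjusted p = 0.083 on centred values, 0.089 with quantile normalisation, 0.058 with the compared groups alone and 0.065 with no variance trend, with UF3GT at -1.33 ± 0.62 and DFR at -1.31 ± 0.66 (adjusted p = 0.62 and 0.70). Ribosomal protein genes had relative median 0.15, adjusted p = 0.031, lost at adjusted p = 0.095 with no dim filter, and ATG8 and ATG3 genes relative median 0.21, adjusted p = 0.031. They had adjusted p = 0.89 with an estimated correlation. The auxin genes HAT2 and GH3.3 were at -1.01 ± 0.40 and -0.78 ± 0.34 (adjusted p = 0.43 and 0.56 as deposited, 0.039 and 0.036 on centred values), and HAT2 had 0.025 with the block. PYK10 was at -0.026 ± 0.28, in 1 of 3 pairs. limma called 123 probe sets higher and 29 lower, 80.9% higher. It called 431 and 113 with the block and 438 and 160 on centred values. Of those called as deposited in total RNA, 51 were higher and 13 lower in both dark and light, against 0.53 and 0.041 for independent lists. The count was 337 without control polysomal dark 1, 89 without dcp5-1 total light 1, 86 without control total light 2, 64 without dcp5-1 total light 2 or control total light 3 and 61 without dcp5-1 total light 3. It was 467, 18 and 12 without replicates 1, 2 and 3. With array weights PYK10 was at 0.091. Calls of flavonoid genes (control 2 or 3, dcp5-1 1, p 0.32), ribosomal protein genes (control 2 or 3, dcp5-1 2, p 0.57), thylakoid genes (control 1, dcp5-1 3, p 0.15), ATG8 and ATG3 genes (control 1, dcp5-1 2 or 3, p 0.22) and plastid-encoded genes (dcp5-1 3, p 0.20) ended without single arrays.

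In light polysomal RNA relative to the array median, dcp5-1 had higher AT5G24240 (4.53 ± 0.57), AT4G38080 (4.50 ± 0.75) and AT5G17820 (3.41 ± 0.36) and lower AT2G16005 (-3.84 ± 0.43), AT1G66800 (-3.47 ± 0.47) and AT5G38030 (-2.68 ± 0.28) (log2, SE, n = 3 and 3, in 3 of 3 pairs). AT5G17820 is a peroxidase. Of the 22 in the expansin list 7 were higher, among them XTH33 (1.31 ± 0.21), EXPA18 (1.94 ± 0.41) and EXPA8 (0.70 ± 0.18), with 10 adjusted over the list alone (relative median 0.60, adjusted p = 1.5e-04, adjusted p = 0.33 with an estimated correlation, and 0.020 with it and the block). The 2 root markers, EXPA18 being 1, did not pass (relative median 0.97, adjusted p = 0.18). The 10 root cell wall genes (1.07, 6 higher, 0 lower) were listed after named genes were seen. AT1G53540 was higher by 1.13 ± 0.21 and AT1G30870 by 1.298 ± 0.36. These 11 had adjusted p from 3.4e-06 to 0.042. As deposited XTH33, EXPA8, AT1G53540 and AT1G30870 had adjusted p = 0.065, 0.33, 0.13 and 0.34. Cold and dehydration genes had relative median 0.57, adjusted p = 0.016, 0.58 with an estimated correlation. Plastid-encoded genes had relative median -0.40, adjusted p = 0.0063, adjusted p = 0.92 with an estimated correlation, with 0 called by limma, 7 at an unadjusted p under 0.05 and 7 lower with the block. Chlorophyll genes had relative median -0.23, adjusted p = 0.0497, adjusted p = 0.76 with an estimated correlation, lost at adjusted p = 0.060 with array weights and 0.076 with the lower 50% left out, 1 lower adjusted over the list alone, and thylakoid genes passed with the block alone, at adjusted p = 0.024 against 0.054 (adjusted p = 0.71 with the block and an estimated correlation). As deposited limma called 139 probe sets higher and 37 lower, 79.0% higher, with the block 437 and 166, and on centred values 476 and 252, 65.4% higher. With array weights the balance turned, with 346 higher and 808 lower, 29.98% higher. The count was 417 without control polysomal dark 1, 97 without control polysomal light 1, 63 without dcp5-1 polysomal light 2 and 85 without dcp5-1 polysomal light 3. It was 522, 21 and 27 without replicates 1, 2 and 3. The call of AT1G30870 ended at adjusted p = 0.068 with no dim filter and 0.078 with array weights. With the compared groups alone calls of EXPA18, EXPA8 and AT1G30870 ended (adjusted p = 0.14, 0.12 and 0.086). Calls of EXPA8 (control 2, dcp5-1 2 or 3, p 0.12), AT1G30870 (control 1 or 3, dcp5-1 1, 2 or 3, dcp5-1 total 2, dcp5-1 total dark 2 or 3, p 0.14), chlorophyll genes (control 1, dcp5-1 3, p 0.39), cold and dehydration genes (control 2 or 3, p 0.082) and plastid-encoded genes (control 2, dcp5-1 3, p 0.57) ended without single arrays.

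No gene or list passed the test for a difference in polysome loading between the genotypes in light. limma called 0 probe sets as deposited, with 83 at an unadjusted p under 0.05, and 0 on centred values, with 338. Processing body and mRNA decay genes had a relative median of -0.18 (adjusted p = 0.57), and chlorophyll genes one of -0.22 (adjusted p = 0.57).

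**Figure D3:**
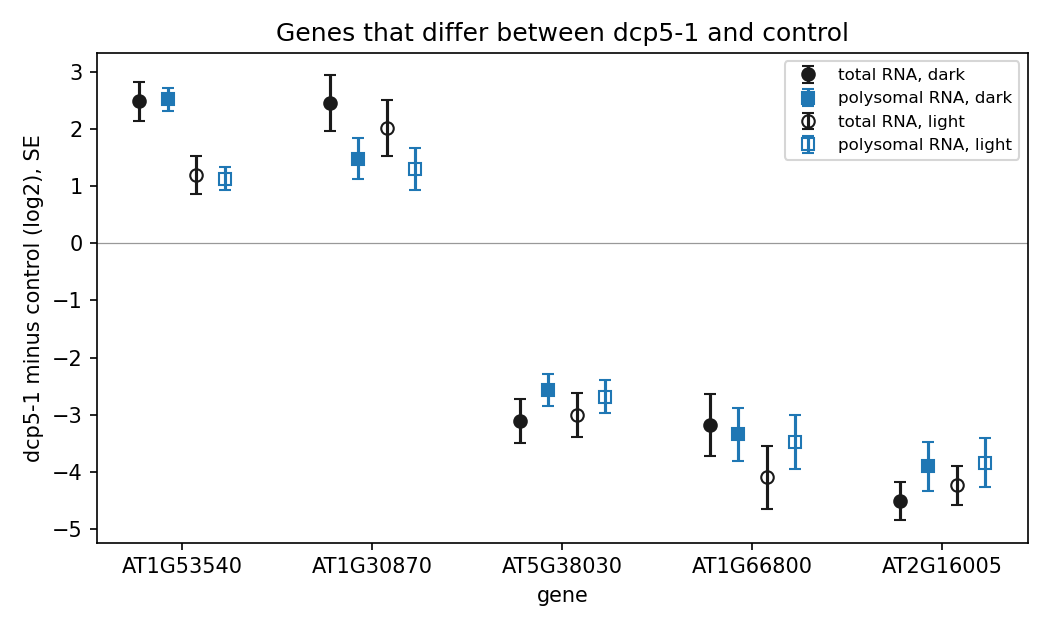
Difference between dcp5-1 and control (log2, with SE, n = 3 and 3) for 5 genes in total and polysomal RNA of dark and light seedlings, polysomal values being relative to the array median. AT5G38030, AT1G66800 and AT2G16005 lie below 0 in all 4 comparisons, and AT1G53540 and AT1G30870 above 0.

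Total-RNA light responses gave 2 calls between genotypes. With offsets kept, the fit found 0 of 67 simulated changes of log2 1. The response of ECS1 was lower in dcp5-1, with a difference of -3.47 ± 0.52 (log2, SE, n = 3 in each of 4 groups, adjusted p = 0.0061, in 3 of 3 pairs). Its level relative to the array median was 5.37 ± 0.20 (SD, n = 3) in dark control and 10.74 ± 0.81 in light control, against 8.64 ± 0.22 and 10.55 ± 0.50 in dcp5-1. The other call was a probe set without a gene name in the table, singled out after its values were seen, at 2.46 ± 0.42 (adjusted p = 0.025). EXPA9 and XTH33 were at 1.82 ± 0.43 and 1.76 ± 0.49, with adjusted p = 0.55 and 0.9999 as deposited and 0.0084 and 0.012 on centred values, EXPA9 having 0.041 with the block. The expansin list had relative median 0.12, adjusted p = 0.0014, 0.78 with an estimated correlation. It was lost at 0.051 with array weights (median -0.10). The median was 0.32 with no dim filter and 0.26 with the lower 50% left out. Adjusted over the list alone 3 were called, while EXPA8 was at 1.21 ± 0.37 (adjusted p = 0.9999). Lower in the list test were thylakoid genes with relative median -0.39, adjusted p = 1.9e-07, photosystem subunits relative median -0.59, adjusted p = 8.6e-04 and light-harvesting genes relative median -0.41, adjusted p = 0.022. With an estimated correlation these lists had adjusted p = 0.46, 0.43 and 0.43. The 3 Calvin cycle genes did not pass (relative median -0.22, adjusted p = 0.31). Single members did not pass, with PSBY (-0.61 ± 0.40), LHCB4.3 (-0.88 ± 0.48) and CaS (-0.76 ± 0.51) each at adjusted p = 0.9999. With no variance trend the call of ECS1 ended (adjusted p = 0.058). Calls of ECS1 (control light 3, dcp5-1 light 1, p 0.053), light-harvesting genes (control dark 2, control light 1, dcp5-1 dark 1, dcp5-1 light 3, p 0.13), photosystem subunits (dcp5-1 dark 1, p 0.079) and the expansin list (control light 1, dcp5-1 dark 1, p 0.13, at -0.061) ended without single arrays.

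Other lists whose total-RNA light response differed were heat shock genes (relative median -1.001, adjusted p = 8.6e-04, 1 lower adjusted over the list alone), dark growth genes (relative median 0.68, adjusted p = 0.0057, 1 higher adjusted over the list alone), chlorophyll genes (relative median -0.31, adjusted p = 0.024), tubulins (relative median 0.31, adjusted p = 0.022, lost at adjusted p = 0.15 with array weights (median 0.17)) and ribosomal protein genes (relative median -0.19, adjusted p = 1.7e-04). These lists had adjusted p = 0.17, 0.22, 0.78, 0.78 and 0.92 with an estimated correlation. AT1G53540 and DFR were at -1.29 ± 0.48 and -1.41 ± 0.94, both with adjusted p = 0.9999, and the flavonoid list passed with the block alone (adjusted p = 0.041, against 0.14, adjusted p = 0.51 with the block and an estimated correlation). limma called 1 probe set higher and 1 lower as deposited, 8 and 2 with the block, and 7 and 1 on centred values. The count was 1 without dcp5-1 total dark 1, 2 or 3, control total dark 2 or 3, control total light 2 or dcp5-1 total light 2 or 3 and 0 without dcp5-1 total light 1 or control total light 3. It was 6, 0 and 0 without replicates 1, 2 and 3. Calls of chlorophyll genes (control dark 2 or 3, control light 1 or 3, dcp5-1 dark 1, dcp5-1 light 3, p 0.48), ribosomal protein genes (control light 1, dcp5-1 dark 2, p 0.24) and tubulins (control light 2, dcp5-1 dark 2, dcp5-1 light 1, p 0.22) ended without single arrays.

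In polysomal RNA the light response of ECS1 differed by -3.91 ± 0.45 in dcp5-1 relative to the array median (log2, SE, n = 3 in each of 4 groups, adjusted p = 1.7e-04), and those of EXPA9 and XTH33 lay 2.19 ± 0.29 and 1.91 ± 0.30 above those of control (adjusted p = 0.0013 and 0.0052), in 3 of 3 pairs. As deposited EXPA9 and XTH33 had adjusted p = 0.072 and 0.12. The flavonoid genes UF3GT and DFR were at -2.69 ± 0.74 and -1.89 ± 0.84 (adjusted p = 0.37 and 0.9999) (relative median -2.31, adjusted p = 6.3e-04, adjusted p = 0.13 with an estimated correlation, 2 lower adjusted over the list alone). THI2.2 was at -2.81 ± 0.85 (adjusted p = 0.56) and LHCB4.3 at -0.90 ± 0.26 (adjusted p = 0.45). As deposited UF3GT and THI2.2 had adjusted p = 0.048 and 0.023. Light-harvesting genes had relative median -0.56, adjusted p = 0.020, 1 lower adjusted over the list alone, thylakoid genes relative median -0.32, adjusted p = 0.0065 and ribosomal protein genes relative median -0.18, adjusted p = 9.5e-05. They had adjusted p = 0.13, 0.65 and 0.65 with an estimated correlation. The expansin list had relative median 0.46, adjusted p = 9.5e-05, 0.21 with an estimated correlation, and 0.015 with it and the block. Its median was 0.24 with no dim filter. Plastid-encoded genes had relative median 0.29, adjusted p = 0.033, 0.75 with an estimated correlation. This was lost at 0.18 with array weights (median 0.18) and 0.14 with the lower 50% left out. limma called 0 probe sets higher and 134 lower as deposited, around a shift of -0.88, and 6 and 2 on centred values. With the block these were 12 and 5801, and 34 and 14. Of the 24 left-out arrays, 23 moved the deposited count over 1.5 times, from 5 without dcp5-1 polysomal dark replicate 3 to 7505 without control polysomal dark replicate 2. It was 63, 0 and 1 without replicates 1, 2 and 3. With the compared groups alone the call of XTH33 ended (adjusted p = 0.073). Calls of light-harvesting genes (control dark 2, control light 2 or 3, dcp5-1 dark 1, dcp5-1 light 3, p 0.15), ribosomal protein genes (control dark 1, control light 1, dcp5-1 dark 2, p 0.27), thylakoid genes (control dark 2, control light 1, dcp5-1 dark 1, dcp5-1 light 3, p 0.46) and plastid-encoded genes (control dark 1 or 2, control light 1 or 3, dcp5-1 dark 3, dcp5-1 light 1 or 2, p 0.99, at -0.062) ended without single arrays.

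For polysome loading, the light response of plastid-encoded genes was higher in dcp5-1 as a list (relative median 0.36, adjusted p = 0.0033, adjusted p = 0.9977 with an estimated correlation, lost at adjusted p = 0.58 with array weights (median 0.074)), 55 of 66 being above 0. ndhG and UF3GT were at 1.95 ± 2.16 and -2.31 ± 1.04, each with adjusted p = 1. limma called 0 probe sets as deposited, with 1743 at an unadjusted p under 0.05, and 1 with the block. It called 0 on centred values, with 145. Without dcp5-1 total dark replicate 3 the deposited count was 1. The call of plastid-encoded genes (control polysomal dark 2, control polysomal light 1 or 3, control total dark 3, control total light 2, dcp5-1 polysomal dark 3, dcp5-1 polysomal light 2, dcp5-1 total dark 1 or 2, dcp5-1 total light 3, p 0.58) ended without single arrays.

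**Figure D4:**
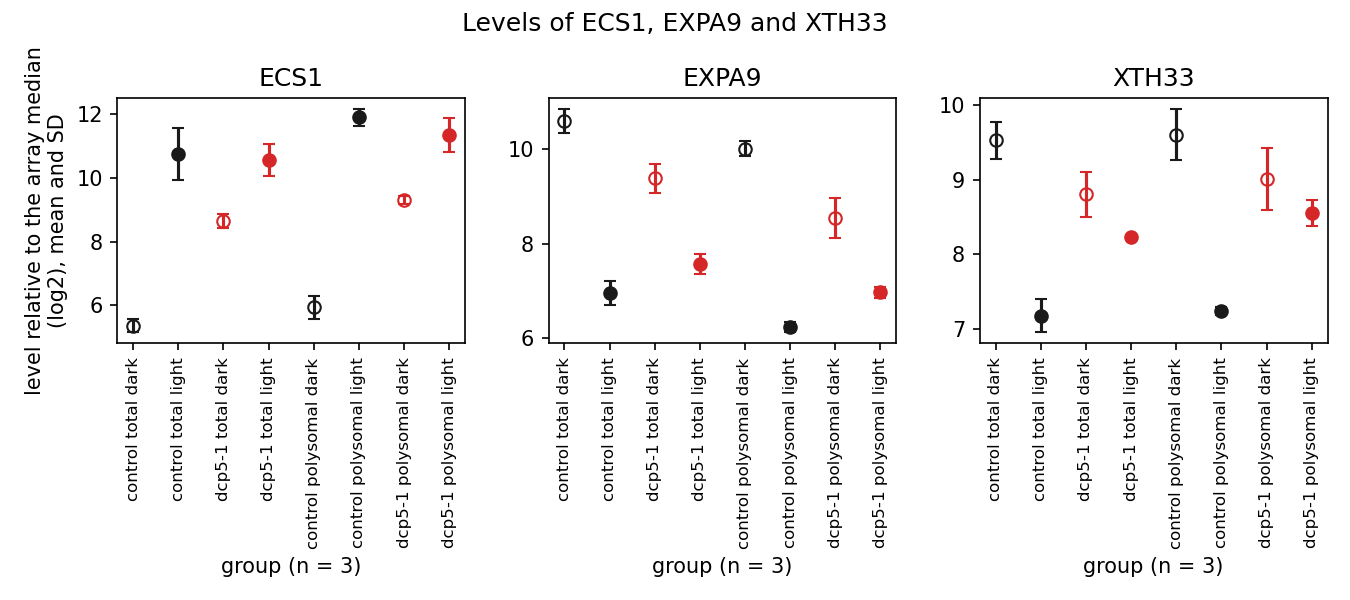
Levels of ECS1, EXPA9 and XTH33 relative to the array median (log2, mean and SD, n = 3) in the 8 groups, control in black, dcp5-1 in red, dark open and light filled. ECS1 lies higher in dark dcp5-1 than in dark control, and EXPA9 and XTH33 lie between the control dark and control light levels in dcp5-1.

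In dark control seedlings, 8 of 66 plastid-encoded genes were lower and 1 higher in polysomal than in total RNA relative to the array median, with 27 and 3 under the block (relative median -0.70, adjusted p = 3.6e-06, adjusted p = 0.71 with an estimated correlation, lost at adjusted p = 0.31 as deposited). Examples were psaA (-2.85 ± 0.33), psbH (-2.62 ± 0.83), psbD (-1.74 ± 0.28) and psbE (-1.67 ± 0.31). Of 6 mitochondrion-encoded genes 3 were lower, among them nad5 (-2.43 ± 0.61) and cox2 (-1.72 ± 0.45) (relative median -1.27, adjusted p = 0.0092, adjusted p = 0.71 with an estimated correlation, lost at adjusted p = 0.78 as deposited). Of 123 ribosomal protein genes 37 were higher and 1 lower, the latter AT2G40010 at -1.09 ± 0.23 (relative median 0.39, adjusted p = 7.5e-09, adjusted p = 0.71 with an estimated correlation). Of 10 processing body and mRNA decay genes 1 was lower, the RNA helicase gene AT2G45810 at -0.69 ± 0.16. EXPB1 and LIL3:2 were also lower, at -1.21 ± 0.30 and -0.62 ± 0.19. Each gene named passed with adjusted p of 0.041 or less, in 3 of 3 pairs. Chlorophyll and thylakoid lists passed with the block alone, at adjusted p = 0.031 for each, against 0.11 and 0.10 (adjusted p = 0.53 and 0.65 with the block and an estimated correlation). As deposited limma called 0 probe sets higher and 16785 lower, around a shift of -2.17. Centred arrays gave 1267 and 841, 60.1% higher, and with the block 2218 and 1560. The call of psbH ended at adjusted p = 0.057 with no dim filter and 0.062 with no variance trend. With the compared groups alone calls of AT2G45810 and LIL3:2 ended (adjusted p = 0.064 and 0.068). Calls of psbH (polysomal 1 or 3, total 1 or 2, p 0.17), cox2 (total 3, p 0.065), nad5 (total 3, p 0.052), AT2G45810 (polysomal 2, p 0.053), EXPB1 (total 3, p 0.064), LIL3:2 (polysomal 2 or 3, total 1 or 3, p 0.14) and mitochondrion-encoded genes (polysomal 1, p 0.14) ended without single arrays.

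Loading changes of light in control and of dcp5-1 in the dark share their dark control arrays, and across 17059 probe sets they correlated at r = 0.40, with a covariance of 0.056. Simulated unchanged groups against the same controls gave r = 0.50 and a covariance of 0.18, both above the observed values, but this takes the arrays as independent. With the residuals of each replicate number kept together, chosen after the result was seen, it gave r = 0.42 and a covariance of 0.050 on centred values, the latter below the observed one, and 0.61 and 0.11 as deposited. A correlation beyond that of the shared controls is left open. THI2.2 and AT1G22690 were the 2 probe sets called higher in both as deposited, against 1.33 for independent lists, and 0 were called in both on centred values, where limma called 0 in each. The correlation was 0.55, 0.47 and 0.53 without control polysomal dark replicates 1 to 3, 0.53, 0.47 and 0.50 without control total dark replicates 1 to 3, and 0.33 without control polysomal light replicate 3. Simulations, 0.48 to 0.52 for independent arrays, used all arrays alone.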

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

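The tests of dark dcp5-1 seedlings lying toward the light state and of genes chosen on dcp5-1 or both genotypes, the block with an estimated correlation and the centred regroupings, were chosen after the result was seen. The light-by-genotype term was passed by 2 probe sets in total RNA and 134 in polysomal RNA as deposited, and by 9, 6 and 1 gene lists in total RNA, polysomal RNA and polysome loading. With an estimated correlation none of these 16 lists passed, the smallest adjusted p being 0.13. On centred total RNA the 2 heat shock genes passed with it, at 0.015, and with the block too the expansin list in polysomal RNA, at 0.015. The light response of ECS1 differed by -3.47 in total RNA and by -3.91 in polysomal RNA relative to the array median. Leaving out arrays or replicate numbers gave 0 to 6 and 0 to 7505 of these probe sets, and the total-RNA call of ECS1 ended without dcp5-1 light replicate 1 or control light replicate 3 (highest adjusted p 0.053). Its dark level in total RNA was 8.64 ± 0.22 in dcp5-1 and 5.37 ± 0.20 in control (log2 relative to the array median, SD, n = 3), and its light levels were 10.55 ± 0.50 and 10.74 ± 0.81.

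Regrouping the 12 samples by genotype within dark and light gave as many calls as the real 2 in 9 of 100 seeded splits for total RNA, with 452 as the highest other. For polysomal RNA it was 15 of 100 splits, with 134 real and 11147 as the highest other, and for polysome loading all 100, with 0 real and 0 as the highest other, where a count of 0 allows no other outcome. Chance is therefore not excluded for the counts of total and polysomal RNA. The regrouping with 452 exchanges the genotypes in light, so it measures the difference between genotypes and not that of their responses. The one with 11147 parts fewer replicate pairs than the real grouping, and 5982 is the highest among those that part all pairs. Counts several times the real one point to a structure of the samples. On centred values the regrouping with 11147 gave 6, so array offsets made its count, and the highest others were 1566 and 1975, both with the genotypes exchanged in light. Without that one they were 396 and 628, and 12 and 13 of 100 splits gave as many calls as the real 8 in each.

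In 1000 strongly responding genes chosen on the control response of 1 replicate number and measured on the others, the dcp5-1 response over the control response was 0.827 (SD 0.041 over 3 rotations) in polysomal RNA and 0.830 (SD 0.031) in total RNA. Choosing genes on the control response favours control. The ratio was 0.855 (SD 0.03) and 0.858 (SD 0.025) in genes chosen on the mean of both genotypes. It was 0.888 (SD 0.035) and 0.893 (SD 0.031) when chosen on dcp5-1, so below 1 without that choice. Rotations share arrays, so these SD understate spread. Light reaching the dark dcp5-1 seedlings may account for part of the pattern and cannot be told apart from it, because dark dcp5-1 lay toward the light state by 0.18 (SD 0.063) in polysomal and 0.17 (SD 0.068) in total RNA, shares of 0.48 and 0.44 of the deficit with SD of 0.18 and 0.20. In light, dcp5-1 lay -0.20 and -0.23 from control in the direction of the response, and -0.093 and -0.12 in genes chosen on dcp5-1. An effect of the mutation remains open as well.

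The 24 dap, lys, phe and thr probe sets for spiked-in RNA, which no comparison uses, had every polysomal array above every total-RNA array. Their mean log2 signals were 10.98 ± 0.84 and 4.50 ± 1.39 (SD, n = 12). Other controls, such as BioB-5 (7.78 and 8.43), were lower.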

How the results depend on the processing

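Alternatives that combine median centring with another choice, the centred arrays without control polysomal dark replicate 1, and deposited against centred values for genes and lists were chosen after seeing the data. Across all alternatives and left-out arrays, 6652 of 6972 values of the 197 printed gene results kept their direction and side of the threshold, 168 lost a call, 133 gained one and 19 reversed. For the 87 list tests that passed, 1413 of 1705 values kept both, 281 lost the call and 11 reversed, and 2 kept it with an estimated correlation. Each alternative that ended or turned a list call, or moved its median over 1.5 times, is given beside it; the filter leaving out the lower 50% ran on 76 of the 87. Calls of printed genes and lists that the replicate block changed are given there as well. Pseudocount alternatives were not run because the values are already log2. Probe sets near the lowest value, where 141 to 605 were tied per array, limit what small signals can show. Why counts moved as below was not tested.

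With the replicate block, counts of called probe sets that moved over 1.5 times were for dcp5-1 428 in dark total, 4399 in dark loading, 544 in light total and 603 in light polysomal, and for light by genotype 10 in total, 5813 in polysomal and 1 in loading. With the replicate block of fraction pairs the count was for dcp5-1 31 in dark loading. With median centring the counts were for light 5124 in control total, 4960 in control polysomal, 0 in control loading and 3731 in dcp5-1 total, for dcp5-1 433 in dark total, 579 in dark polysomal, 0 in dark loading, 598 in light total and 728 in light polysomal, for light by genotype 8 in total and 8 in polysomal, and 2108 for polysome over total. With quantile normalisation the counts were for light 5079 in control total, 4768 in control polysomal, 0 in control loading and 3873 in dcp5-1 total, for dcp5-1 429 in dark total, 525 in dark polysomal, 0 in dark loading, 618 in light total and 739 in light polysomal, for light by genotype 10 in total and 9 in polysomal, and 1915 for polysome over total.

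With array weights the counts were for light 7112 in control total, 7634 in control polysomal, 5611 in control loading, 5245 in dcp5-1 total, 4223 in dcp5-1 polysomal and 1 in dcp5-1 loading, for dcp5-1 1431 in dark total, 1667 in dark polysomal, 14 in dark loading, 2092 in light total and 1154 in light polysomal, for light by genotype 87 in total and 984 in polysomal, and 0.61 for the shared loading r. The share higher was then 46.95%, 49.7% and 73.05% for light in control total, dcp5-1 total and dcp5-1 polysomal RNA, and 55.6%, 55.2% and 29.98% for dcp5-1 in dark total, light total and light polysomal RNA. With only the arrays of the groups compared the counts were for light 4635 in control total, 8783 in control polysomal, 3904 in control loading and 3991 in dcp5-1 total, for dcp5-1 212 in dark total, 948 in dark polysomal, 0 in dark loading and 626 in light total, and for light by genotype 5 in total and 2 in polysomal. With no dim filter the values were for dcp5-1 1 in dark loading, for light by genotype 26 in polysomal, and 0.47 for the shared loading r. With the lower 50% of probe sets left out the values were for dcp5-1 1 in dark loading and 111 in light polysomal, for light by genotype 490 in polysomal, and 0.28 for the shared loading r. With no variance trend the count was for light by genotype 0 in total.

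With median centring and the replicate block together the counts were for light 6596 in control total, 6406 in control polysomal, 0 in control loading, 5106 in dcp5-1 total, 5076 in dcp5-1 polysomal and 1 in dcp5-1 loading, for dcp5-1 1137 in dark total, 1623 in dark polysomal, 0 in dark loading, 1506 in light total and 1731 in light polysomal, for light by genotype 42 in total and 48 in polysomal, and 3778 for polysome over total. With median centring and only the arrays of the groups compared they were for light 4667 in control total, 3417 in control polysomal, 0 in control loading and 3915 in dcp5-1 total, for dcp5-1 229 in dark total, 208 in dark polysomal, 0 in dark loading, 629 in light total and 315 in light polysomal, for light by genotype 5 in total and 5 in polysomal, and 1078 for polysome over total. With median centring and control polysomal dark replicate 1 left out they were for light 4275 in control polysomal and 1 in control loading, for dcp5-1 398 in dark polysomal and 1 in dark loading, for light by genotype 12 in polysomal, and 2282 for polysome over total and 0.55 for the shared loading r. With median centring and the replicate block of fraction pairs they were for light 0 in control loading, for dcp5-1 0 in dark loading, and 4018 for polysome over total.

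Leaving out each array or each replicate number in turn gave for light 1362 to 4259 in control total, 0 to 13854 in control loading, 764 to 2947 in dcp5-1 total and 1214 to 4069 in dcp5-1 polysomal, for dcp5-1 9 to 364 in dark total, 1123 to 13109 in dark polysomal, 0 to 6805 in dark loading, 12 to 467 in light total and 21 to 522 in light polysomal, for light by genotype 0 to 6 in total, 0 to 7505 in polysomal and 0 to 1 in loading, and 0.33 to 0.55 for the shared loading r.

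As deposited, SDP1 in light in control polysomal RNA was at 0.44 and UF3GT in light in control loading at 1.22, where both lay below 0 relative to the array median. With array weights PYK10 in dcp5-1 was at 0.019 in dark and 0.091 in light total RNA, the auxin list in light in control total RNA at 0.017 and the expansin list in light by genotype in total RNA at -0.10, and with no dim filter the auxin list in light in dcp5-1 total RNA at 0.19. Leaving out arrays, these values also changed sign: UF3GT in control loading from -0.81 to 1.04, PYK10 from -0.20 to 0.032 in dark and from -0.13 to 0.095 in light, and the auxin list in dcp5-1 from -0.27 to 0.042. Lists that changed sign were plastid-encoded genes in dcp5-1 in dark loading, from -0.65 to 0.049, and in light by genotype in polysomal RNA, from -0.062 to 0.58. The others were ribosomal protein genes in dcp5-1 in light total RNA, from -5.7e-04 to 0.31, and the expansin list in light by genotype in total RNA, from -0.14 to 0.25.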

Other observations

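The root list, the spike test, the undone factors and the polysomal share were tests chosen after the result was seen. On centred values 115 probe sets were higher and 33 lower in dcp5-1 than in control in all 4 direct comparisons. An example, picked after its values were seen, is AT4G36430 (3.69, 3.81, 3.58, 3.26), with log2 changes in dark total, dark polysomal, light total and light polysomal RNA. The MATE transporter AT5G38030 was lower in all 4, -3.11, -2.57, -3.00, -2.68.

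For these genes a chromosome segment linked to DCP5 was weighed first: 0 percent of the 76 with a locus lay within 200 genes of DCP5 (95% upper bound 4.74%), against 1.097% of the genes tested, which argues against it. Root tissue in the aerial parts is left open. The 10 root cell wall and peroxidase genes had relative median 0.84 in dark total RNA (5 higher, 1 lower). The list was written after the named genes were seen, so its rise was built in and decides nothing. The 2 root markers fixed beforehand did not pass in any of the 4 comparisons, the lowest adjusted p being 0.13. Of these, PYK10 was at -0.061 ± 0.28 in dark and -0.026 ± 0.28 in light total RNA. It is also active in young shoots, so this excludes little. EXPA18 was at 1.595 and 1.003 there, and called in light polysomal RNA (1.94). Both are also among the 10, so these tests overlap. An effect of the mutation stays open as well.

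For the array-wide rise of polysomal signal in control light, the median loading change of 1.25 (SD 0.47 over the pairs) was -0.025 with the factor of each polysomal array undone, but all arrays then have nearly the same trimmed mean, so this test decides nothing. That the factors were set from the 24 spike probe sets is argued against. Their signal varied more over the 12 polysomal arrays as deposited than with the factors undone, by 1.92 times in SD (0.84 and 0.44). A larger polysomal share of mRNA in control light may underlie the factors and cannot be told apart from a technical scaling, since 3 pairs against 3 give an exact permutation p of 0.1 at best and the source of the factors is not given in the sources used here.

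Each comparison of 3 arrays or pairs with 3 has 10 splits, which are too few for a share under 0.05. The real split alone, 1 of 10, gave as many calls in the following, with the real count and the highest of the other splits: 2989 and 0 for light in control total RNA, 13310 and 4021 in control polysomal RNA, 11354 and 0 in control loading, 1999 and 0 in dcp5-1 total RNA, and 2677 and 1 in dcp5-1 polysomal RNA. For dcp5-1 against control these were 98 and 0 in dark total RNA, 10143 and 6593 in dark polysomal RNA, 2 and 1 in dark loading, 152 and 0 in light total RNA and 176 and 1 in light polysomal RNA. For polysome over total they were 16785 and 101. For light in dcp5-1 loading and dcp5-1 in light loading all 10 splits gave the real count of 0. The other splits with 4021, 6593 and 101 calls part fewer replicate pairs than the real one. Among splits that part all pairs the highest other count was 1, in light polysomal RNA of dcp5-1 against control and in polysome over total.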
